A study of Arabidopsis thaliana with 11 samples.

How the data were processed

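Poly-A RNA of whole light-grown seedlings, 4 days old, of Columbia wild type (WT) and of an estradiol-inducible SPCH line (iSPCH) was measured by sequencing, in 11 libraries of 6 groups. RNA was taken with RNeasy columns and treated with DNaseI, and the libraries were made with the TruSeq kit. Strand is not stated. The submitters' processing notes name CASAVA 1.8, TopHat, DESeq and the TAIR10 genome without giving roles. Versions of TopHat and DESeq, and the counting tool and its gene models, are not given in the sources used here.

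The deposited file holds 1 signal value per gene and group, 33602 genes by 6 columns, which the authors made as group means of normalised read counts. It holds no value per library, so it was another unit than the design, written before the data were examined, had assumed. That design named edgeR on counts, and limma-trend on log2 values if the file held no counts. To the 10 significant digits deposited, every value of the untreated WT column is a whole multiple of a single step. Within the same rounding, every value of the other columns is a whole multiple of a first step plus a whole multiple of a second. Whole reads of both libraries of a group follow from this for 33484 genes. For 118 abundant genes, each with a highest group mean of 17170 or more, several pairs of whole reads give the same mean. They hold 31.9% of all reads and were not tested. On simulated means the recovery gave 1 solution for 99.5 to 100% of genes, and 100% of those were right. Values moved at random had a solution in 0 to 0.1% of cases. The order of the libraries within a pair is arbitrary, and all 6 columns were used (0 columns per sample were not used). The authors' means, where printed, are pooled over a group and carry no spread.

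Recovered reads were divided by the authors' size factors and analysed as log2 of the value plus 1 with limma 3.58.1 in R 4.3.3, using limma-trend with robust variance and 1 coefficient per group. Robust variance was settled after fits with and without it had been run. Genes with a CPM of at least 1 in at least 2 of the 11 libraries were tested, 19660 in all, at a Benjamini-Hochberg FDR of 0.05 per comparison. The 12 comparisons were iSPCH against WT at 0 h, 6 h, 8 h and for the mean of 6 h and 8 h, each line at 6 h and 8 h against 0 h, iSPCH at 8 h against 6 h, and 3 differences between such contrasts. WT 0 h, a single library, was assumed to vary like the other groups. Of 15 gene lists with 213 genes, written down before the data were examined, 14 were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. SPCH was left out of its list. Members left out for low reads numbered 3 in the stomatal list, 4 in touch, wound and defence, 2 in auxin and cytokinin, and 1 each in brassinosteroid signalling, cell cycle, hypoxia, root, trichome and root hair, vascular and water deficit. Members left out for several solutions numbered 1 in the guard cell list and all 10 of the photosynthesis list.

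The genes named were set by a rule from before the data were examined. It took SPCH, and the 12 higher and 12 lower genes with the largest mean change among those past FDR 0.05 at both hours. Those had to go in the same direction, with every iSPCH library beyond every WT library of the hour and a mean CPM of at least 2 in the higher group. It also took every called stomatal gene, up to 4 members of each other list with the smallest p at 8 h, and 5 higher and 5 lower genes of each other comparison. Once the values were known this was extended to differences between contrasts, where every combination of libraries had to keep the sign and the highest group that enters positively had to have a mean CPM of at least 2. Copies were sought with BLAST+ 2.17.0 (at least 95% identity over at least 100 bases). Of 143 named genes 7 have such a copy and 39 overlap another gene. The TAIR10.1 annotation gave names and positions for 32835 of the 33602 loci, and 767 were not matched, of which 146 are mitochondrial and 133 chloroplast loci. The table holds no coordinates, so no other difference from the authors' TAIR10 models was checked.

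With the 118 abundant genes divided as evenly as possible, depth was 15.55M to 32.81M assigned reads a library, of which 11043748 to 21401059 lay in the other genes, and the median SE of a line difference at 6 h or 8 h was 0.123. In simulated data with 200 changed genes the same fit found 59.7%, 87.9% and 100% of changes of 1.5-, 2- and 4-fold at 6 h, and 65.7%, 90.9% and 100% at 8 h. False calls were 9 of 172 and 13 of 182. The simulated spread followed the trend with abundance, with no spread particular to a gene, no correlation between genes and no deviating library. These rates hold for that setting only. Libraries of a pair differed by 3.21 to 7.20 times the sampling variance among genes with at least 20 reads. Alternatives were an added count of 0.1 or 5, scaling by library size or TMM, no filter or a mean CPM of at least 5, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, only the compared groups, no robust variance, abundant genes at their most even split, an FDR of 0.01, a 2-fold minimum, and each of the 10 libraries of groups with 2 left out in turn. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.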

Results

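Messenger RNA was sequenced from whole seedlings of Arabidopsis thaliana that were 4 days old and had grown in light. There were 2 lines, the Columbia wild type (WT) and an inducible line (iSPCH). The latter carries ESTpro:SPCH1-4A-YFP, a tagged variant of the stomatal lineage regulator SPEECHLESS (SPCH) under estradiol control. Seedlings of both lines were sampled untreated (0 h) or after 6 h or 8 h in 10 µM estradiol. Each line and hour had 2 libraries, except untreated WT with 1, which made 11 libraries in 6 groups. The libraries of a pair are called A and B, in arbitrary order, because the replicate numbers of the labels could not be traced to the values. Assigned reads, with genes that could not be split between libraries divided as evenly as possible, came to 32.81M for WT 0 h, 25.11M and 25.03M for iSPCH 0 h, 25.37M and 23.24M for WT 6 h, and 28.43M and 15.55M for iSPCH 6 h. They came to 27.04M and 20.47M for WT 8 h and to 20.39M and 18.48M for iSPCH 8 h, with A before B. The first principal component held 78.5% of the variance and set the 3 untreated libraries apart from the other 8. The second, with 7.85%, parted iSPCH from WT at 6 h and 8 h, and the third, with 3.39%, set iSPCH 6 h B, the shallowest library, apart.

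Gene values below are normalised read counts per library, or log2 fold changes with their standard error (SE). Each group has n = 2 libraries, and WT 0 h has n = 1. Adjusted p values come from limma over 19660 genes. The labels do not say whether the libraries of a pair came from separate cultures, so the p values measure only the spread between these samples.

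The series title asks what SPCH does in setting up the self-renewing cells of the stomatal lineage, so the main question is which transcripts differ once SPCH is switched on. The control is WT without the construct. Line differences under estradiol can thus include effects of the construct other than SPCH, which cannot be told apart here. SPCH (AT5G53210; chromosome 5, 21586219 to 21589255 in TAIR10.1) had normalised read counts of 37224 and 37521 in iSPCH at 6 h and of 41638 and 39757 at 8 h. The WT libraries held 103 and 130 at 6 h and 99.5 and 141 at 8 h. Before induction WT held 178, and iSPCH held 170 and 232. The line difference was 8.32 ± 0.19 at 6 h (adjusted p = 1.86e-07) and 8.41 ± 0.19 at 8 h (adjusted p = 4.49e-08), or 320-fold and 341-fold. Reads of the transgene and of the native gene were not told apart. Between 6 h and 8 h SPCH in iSPCH differed by 0.12 ± 0.19 (adjusted p = 0.781).

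**Figure D1:**
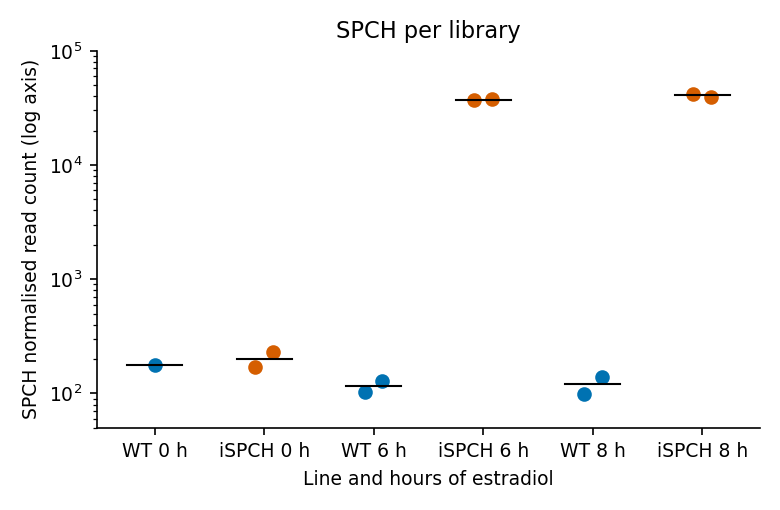
SPCH normalised read count (log axis) in each of the 11 libraries, by line and hours of estradiol, with points for libraries and bars for group means. The 4 induced iSPCH libraries lie between 37224 and 41638, and the other 7 between 99.5 and 232.

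After 6 h of estradiol EPF2 and TMM, regulators of early stomatal development, stood far higher in iSPCH than in WT. EPF2 (AT1G34245; chromosome 1, 12472868 to 12473974), a secreted peptide that limits the number of lineage cells, was higher by 3.36 ± 0.38 (adjusted p = 0.000501). TMM (AT1G80080), a receptor-like protein that helps to perceive such peptides, was 9.84-fold higher (adjusted p = 2.40e-10). It held 2746 and 2596 in iSPCH against 279 and 263 in WT. AT1G12845, which codes for an uncharacterised protein, was higher by 3.83 ± 0.13 (adjusted p = 2.40e-10). The peroxidase genes AT1G05240 and AT1G05250 were lower by -2.54 ± 0.32 and -2.55 ± 0.32. They are identical over 1492 bases and share reads, so they count as 1 observation. Over all genes 226 were higher and 697 lower in iSPCH (923 at FDR 0.05), of which 41 and 91 changed at least 2-fold. The count was 538 with only the compared groups in the fit, 228 without WT 6 h A, 283 without WT 6 h B, 325 without iSPCH 6 h B and 1407 without iSPCH 6 h A. Scaling by library size alone moved the median gene by 0.10 and turned the split to 713 higher and 426 lower.

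After 8 h EPF2, TMM and POLAR stood far higher in iSPCH than in WT, and genes of root hairs were among the lowest. AT1G12845 was higher by 5.40 ± 0.13 (adjusted p = 3.25e-12) and EPF2 by 4.75 ± 0.38 (adjusted p = 9.28e-06). TMM was higher by 3.96 ± 0.11 (adjusted p = 9.28e-12) and POLAR (AT4G31805), a marker of polarity in dividing lineage cells, by 3.95 ± 0.16 (adjusted p = 1.27e-09). COBL9 (AT5G49270) and EXP7 (AT1G12560), a COBRA-like protein and an expansin of growing root hairs, were lower by -3.95 ± 0.33 (adjusted p = 4.67e-06) and -3.60 ± 0.32 (adjusted p = 1.57e-05). COBL9 stood at 2.12 and 5.77 in iSPCH against 64.6 and 75.9 in WT. In all, 933 genes were higher and 1169 lower (2102), of which 249 and 164 changed at least 2-fold. The count was 1112 without WT 8 h B, 1266 without iSPCH 8 h B and 1269 without iSPCH 8 h A. Scaling by library size alone moved the median gene by 0.12 and gave 1730 higher and 644 lower.

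Of the genes called at 6 h, 131 were also called higher and 382 also called lower at 8 h, where 10.7 and 41.4 would be shared if the calls were independent. Both comparisons use the same estimate of each gene's spread, so calls can coincide more often than that without a shared change. Opposite calls were made for 2 and 3 genes. The 12 genes furthest above WT in iSPCH at both hours held EPF2, TMM, POLAR and BASL (AT5G60880). BASL, a cortical protein that marks the asymmetric division of the lineage, had 1.14 ± 0.21 at 6 h and 3.04 ± 0.21 at 8 h. CPL3 (AT4G01060), a small MYB protein related to CAPRICE, had 1.88 ± 0.26 and 2.64 ± 0.26. AT2G25460, AT5G67020 and AT2G15420 have no functional name. AT2G25460 had 2.20 ± 0.20 and 2.89 ± 0.20, AT5G67020 had 1.56 ± 0.27 and 2.74 ± 0.27, and AT2G15420 had 2.16 ± 0.31 and 3.35 ± 0.31. AT1G67105, QQS (AT3G30720) and SADHU3-2 (AT3G42658) complete the 12 with AT1G12845, but these 3 already differed between the lines at 0 h, by 2.57, 2.46 and 2.51. Of the 12 genes furthest below WT, 2 were already past FDR 0.05 between the lines at 0 h. Among the 12, AT3G31540 had 0 reads in both iSPCH libraries at 0 h and at 8 h, against 102 and 88 reads in WT at 8 h. Its lack of reads in iSPCH thus dates from before induction. AT3G31540 also has a near-identical copy (95.73% identity over 656 bases). AT4G30330 was lower by -2.91 ± 0.32 at 6 h, by -3.33 ± 0.32 at 8 h and by -3.89 ± 0.39 already at 0 h. AT4G04223, with near-identical copies elsewhere in the genome, was lower by -2.36 ± 0.36 and -2.08 ± 0.36. Calls at 6 h were lost for BASL without WT 6 h A (adjusted p = 0.0662) or B (0.0515), AT5G67020 without WT 6 h A (0.0557), AT1G05240 without WT 6 h B (0.0508), and AT4G04223 without iSPCH 6 h B (0.0524) or WT 6 h A (0.0534).

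The other genes furthest below WT at both hours include several known from root hairs. PRP3 (AT3G62680), a proline-rich wall protein, was lower by -2.12 ± 0.42 at 6 h and -3.80 ± 0.42 at 8 h. RHS19 (AT5G67400), a root hair specific gene, was lower by -2.18 ± 0.33 and -3.24 ± 0.33. ACA9 (AT3G21180), a calcium pump, was lower by -1.73 ± 0.37 and -2.83 ± 0.37. COW1 (AT4G34580), a phosphatidylinositol transfer protein needed for root hair growth, was lower by -1.37 ± 0.30 and -2.53 ± 0.30. COBL9 and EXP7 were lower at 6 h too, by -1.64 ± 0.33 and -1.22 ± 0.32. Over the alternatives these ranged from -2.00 to -1.27 and from -1.85 to -0.58. Many root hair genes stood lower in iSPCH 6 h B, the shallowest library, than in A, while RHD6, RSL4, RSH2 and RSH3 did not. The size of the fall at 6 h therefore rests in part on library B. Several of the root hair genes also fell within WT. By the authors' means WT went from 592 at 0 h to 171 at 8 h for PRP3, from 214 to 70.3 for COBL9 and from 233 to 84.7 for EXP7. In iSPCH these means went from 496 to 11.7, from 195 to 3.95 and from 204 to 6.12. AT2G47540, of the Pollen Ole e allergen family, was lower by -0.90 ± 0.23 and, at 8 h, by -2.91 ± 0.23. Their calls at 8 h held in each refit at FDR 0.05 in which the gene was tested, while several at 6 h were lost. Without WT 6 h A those of PRP3, COBL9, EXP7, ACA9, COW1 and AT2G47540 were lost (adjusted p = 0.181, 0.101, 0.238, 0.161, 0.199 and 0.176). Without WT 6 h B those of PRP3, COBL9, EXP7, ACA9 and AT2G47540 were lost (adjusted p = 0.186, 0.0932, 0.226, 0.0903 and 0.238). Without iSPCH 6 h B those of COBL9, EXP7, ACA9, COW1 and AT2G47540 were lost (adjusted p = 0.102, 0.271, 0.122, 0.161 and 0.121). The calls of PRP3, EXP7 and AT2G47540 were also lost without single libraries of other groups (adjusted p = 0.0616, 0.0833 and 0.0546 without WT 8 h A). With only the compared groups PRP3, EXP7 and COW1 were lost (adjusted p = 0.0785, 0.160 and 0.0758).

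**Figure D2:**
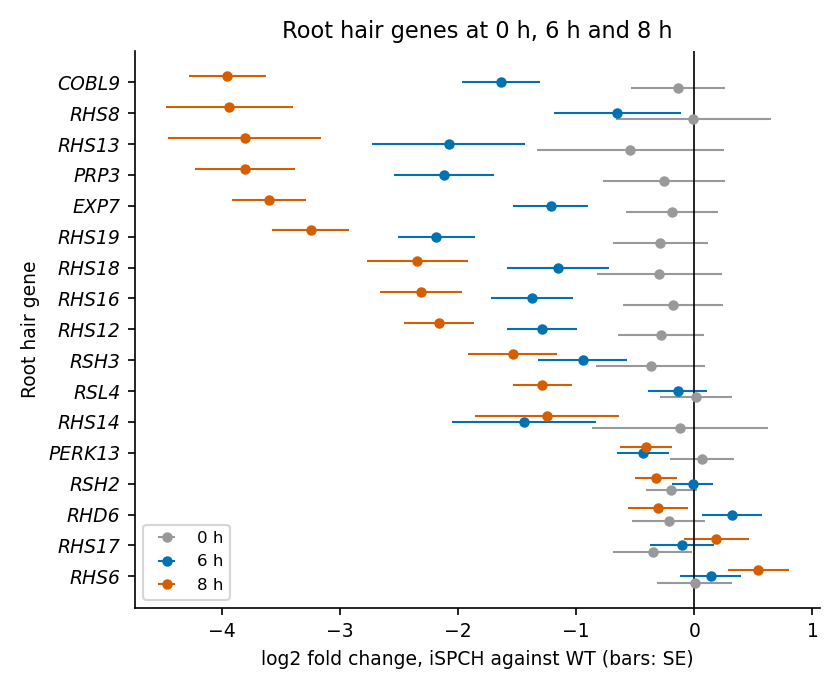
Log2 fold change between iSPCH and WT at 0 h, 6 h and 8 h for the 17 tested root hair genes (points, with SE as bars). The median over the 17 is -0.20 at 0 h, -1.15 at 6 h and -2.16 at 8 h, and 11 of them were lower past FDR 0.05 at 8 h.

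The stomatal lineage list, which holds regulators, receptors, peptides and polarity proteins of the pathway, had more members called higher than lower at both hours. Its median was 0.31 at 6 h and 0.13 at 8 h, and camera's direction was up. At 6 h 11 of its 27 tested members were higher and 1 lower (14 adjusted over the list alone). Camera gave adjusted p = 3.26e-09 (adjusted p = 0.165 with an estimated correlation). At 8 h 12 were higher and 2 lower (14 adjusted over the list alone), with a camera adjusted p = 3.15e-09 (adjusted p = 0.0832 with an estimated correlation). ICE1 (AT3G26744) and SCRM2 (AT1G12860), partner transcription factors of SPCH, were higher by 1.19 ± 0.08 and 0.77 ± 0.08 at 6 h and by 1.71 ± 0.08 and 1.44 ± 0.08 at 8 h. The receptor kinases ERL1 (AT5G62230) and ERL2 (AT5G07180) were higher by 0.83 ± 0.19 and 0.54 ± 0.12 at 6 h and by 2.12 ± 0.19 and 1.101 ± 0.12 at 8 h. SOL1 (AT3G22760) and TCX2 (AT4G14770), a pair of CXC-domain regulators of the lineage, reached 2.36 ± 0.21 and 1.197 ± 0.11 at 8 h. At 6 h SOL1 had 1.08 ± 0.21, and TCX2 with 0.29 ± 0.11 was not past the threshold (adjusted p = 0.178). POLAR had 1.77 ± 0.16 at 6 h, the peptide gene CLE9 (AT1G26600) had 1.09 ± 0.22 and 2.11 ± 0.22, and the homeobox gene HDG2 (AT1G05230) 0.34 ± 0.09 and 0.72 ± 0.09. These are differences from WT, where several of the genes fell after 0 h. By the authors' means BASL in iSPCH had 59.3 at 0 h and 51.9 at 6 h, against 55.5 and 22.9 in WT. In iSPCH ERL1 and HDG2 at 6 h, and ERL2 and TCX2 at both hours, were also below their 0 h means. ICE1, SCRM2, TMM, EPF2, POLAR, SOL1 and CLE9 were above theirs in iSPCH at both hours. EPFL9 (AT4G12970), the peptide stomagen that promotes stomata, was lower by -1.38 ± 0.20 at 6 h and -0.82 ± 0.20 at 8 h. The receptor kinase ER (AT2G26330) was lower by -0.44 ± 0.10 at 8 h. The later regulators MUTE (AT3G06120) and FAMA (AT3G24140) had -0.05 ± 0.42 and 0.01 ± 0.09 at 8 h, with 8 to 12 reads of MUTE a library, and EPF1 (AT2G20875) had 0.57 ± 0.34 (adjusted p = 0.341).

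Several of these smaller calls were lost in refits, many of which had fewer libraries, while the values kept their sign. Over the alternatives at 6 h ERL1 had 0.63 to 1.03, ERL2 0.49 to 0.64 and SOL1 0.82 to 1.35. CLE9 had 0.98 to 1.19 and HDG2 0.31 to 0.44. At 8 h EPFL9 had -0.97 to -0.67 and ER -0.59 to -0.30. The lost calls therefore do not show that 1 library carried them. At 6 h ERL1, ERL2, SOL1, CLE9 and HDG2 were no longer called without WT 6 h A (adjusted p = 0.258, 0.163, 0.0938, 0.0868 and 0.212), nor ERL2, SOL1, CLE9 and HDG2 without WT 6 h B (0.117, 0.0696, 0.0666 and 0.237). ERL1, ERL2 and HDG2 were lost without iSPCH 6 h A (adjusted p = 0.0957, 0.0680 and 0.0589), and ERL2 and HDG2 without iSPCH 6 h B (0.0656 and 0.210). ERL2 and HDG2 were also lost with DESeq2 (adjusted p = 0.0629 and 0.187), and HDG2 in 11 of 22 alternatives. At 8 h EPFL9 and ER were lost without iSPCH 8 h A (adjusted p = 0.117 and 0.157) or WT 8 h B (0.0835 and 0.166), EPFL9 without WT 8 h A (0.0710) or with DESeq2 (0.0689), and ER with library size alone (0.0776). The other stomatal calls at 8 h, of EPF2, TMM, POLAR, BASL, ICE1, SCRM2, ERL1, ERL2, SOL1, CLE9, HDG2 and TCX2, held in each refit at FDR 0.05 in which the gene was tested. HDG2 alone of these was under a 2-fold minimum at 8 h.

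**Figure D3:**
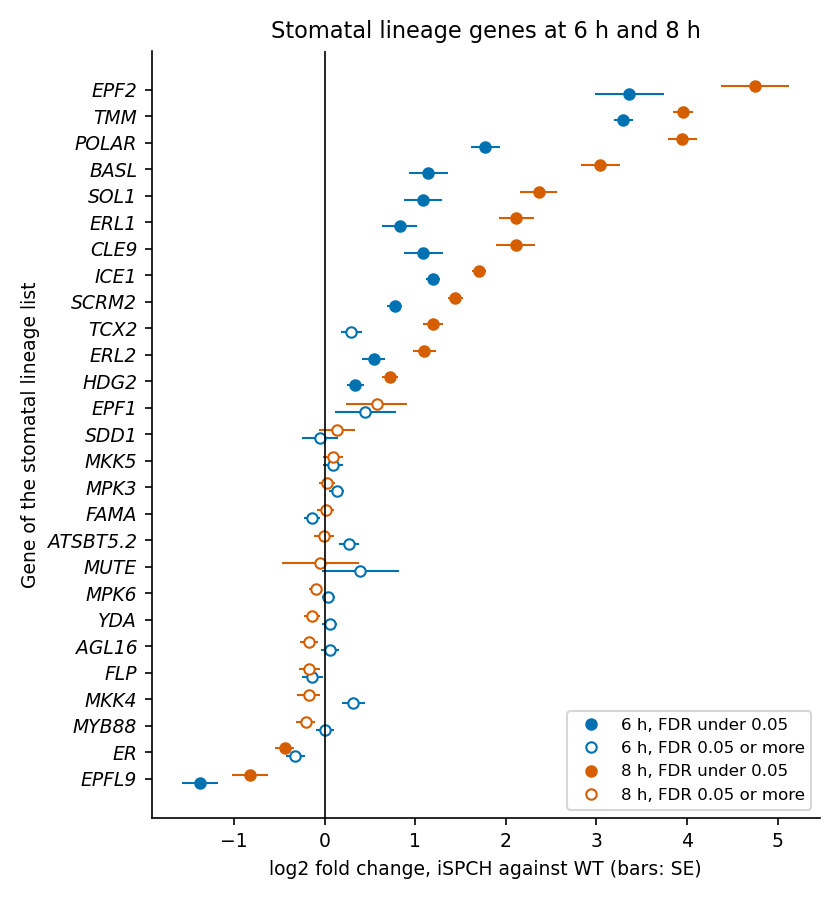
Log2 fold change between iSPCH and WT of the 27 tested stomatal lineage genes other than SPCH at 6 h and 8 h, with SE as bars and filled points for FDR under 0.05. EPF2, TMM, POLAR and BASL lie furthest to the right at 8 h, and EPFL9 and ER are the filled points to the left of 0.

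Genes of finished guard cells were not higher along with the regulators. Of 11 tested members of the guard cell list, 0 were higher and 3 lower at both hours (3 adjusted over the list alone each time). TGG2 (AT5G25980), a myrosinase, was lower by -0.73 ± 0.12 and -0.74 ± 0.12. ALMT12 (AT4G17970), an anion channel of closing stomata, was lower by -1.24 ± 0.22 and -0.99 ± 0.22, and CYP86A2 (AT4G00360), a cutin enzyme, by -0.65 ± 0.15 and -0.56 ± 0.15. Camera called the list lower at 6 h (adjusted p = 0.0114, adjusted p = 0.165 with an estimated correlation) but not at 8 h (adjusted p = 0.352, adjusted p = 0.396 with an estimated correlation). The epidermis and cuticle list was lower, with 3 of 7 members called at 6 h and 5 at 8 h (6 adjusted over the list alone at each). ABCG12 (AT1G51500), an exporter of cuticular wax, was lower by -0.53 ± 0.08 and -0.62 ± 0.08, and the fatty acid elongase FDH (AT2G26250) by -0.36 ± 0.08 and -0.47 ± 0.08. ATML1 (AT4G21750) and PDF2 (AT4G04890), homeobox genes of epidermal identity, were lower by -0.34 ± 0.07 and -0.32 ± 0.09 at 8 h. Camera gave this list adjusted p = 2.44e-05 and 0.000139 (adjusted p = 0.165 and 0.295 with an estimated correlation). At 6 h FDH was no longer called without WT 6 h A, WT 6 h B or iSPCH 6 h B (adjusted p = 0.133, 0.162 and 0.165), nor CYP86A2 without any of these (0.178, 0.146 and 0.123), nor TGG2 and ALMT12 without WT 6 h B (0.0553 and 0.0518). At 8 h ALMT12, ATML1 and PDF2 were lost without iSPCH 8 h A (adjusted p = 0.0604, 0.0625 and 0.262), CYP86A2, ATML1 and PDF2 without WT 8 h A (0.132, 0.0565 and 0.173), ALMT12, CYP86A2 and PDF2 without WT 8 h B (0.107, 0.165 and 0.0681), and CYP86A2 without iSPCH 8 h B (0.203). With library size alone ATML1, PDF2 and CYP86A2 were lost at 8 h (adjusted p = 0.0660, 0.176 and 0.0501, with -0.22 and -0.20 for the first 2) and FDH at 6 h (0.0635). The camera call of the guard cell list at 6 h was lost with a mean CPM of at least 5 (adjusted p = 0.0794).

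The trichome and root hair patterning list shares its called members with the 17 root hair genes, so it is no separate evidence. Of its 10 tested members 3 were lower at 6 h and 4 at 8 h, with 0 higher (3 and 4 adjusted over the list alone). Camera gave adjusted p = 0.0405 and 9.30e-05 (adjusted p = 0.165 and 0.0832 with an estimated correlation). The 4 were EXP7, COBL9, PRP3 and RSL4 (AT1G27740), the last a regulator of root hair length with -1.29 ± 0.25 at 8 h. The root tissue list, with markers of other root cell types, had 0 of 8 members called at 6 h (0 adjusted over the list alone, camera adjusted p = 0.487, adjusted p = 0.548 with an estimated correlation). At 8 h 3 were lower (3 adjusted over the list alone, camera adjusted p = 0.0956, adjusted p = 0.295 with an estimated correlation). Among these CASP1 (AT2G36100), of the Casparian strip, had -0.67 ± 0.15 and SHR (AT4G37650) -0.41 ± 0.11. The vascular list had 1 of 8 lower at 6 h and 2 at 8 h (4 and 5 adjusted over the list alone). Camera gave it adjusted p = 0.0405 and 0.0132 (adjusted p = 0.325 and 0.295 with an estimated correlation). Its member HB-8 (AT4G32880), a regulator of the procambium, had -0.57 ± 0.10 at 8 h. The camera calls at 6 h were lost for the patterning list without WT 6 h A, WT 8 h A or WT 8 h B (adjusted p = 0.106, 0.0637 and 0.0655) and for the vascular list without WT 6 h A or iSPCH 6 h A (0.187 and 0.174) or with library size alone (0.0616) or a mean CPM of at least 5 (0.0604), and that of the vascular list at 8 h without WT 8 h B (0.134). The calls of CASP1 and SHR were lost without iSPCH 8 h B (adjusted p = 0.0943 and 0.0981), WT 8 h B (0.0646 and 0.0951) or WT 8 h A (0.0938 and 0.117), and that of SHR without iSPCH 8 h A (0.102), with library size alone (0.0946) or with DESeq2 (0.116).

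The genes of the photosynthesis list, 10 in number, were among the abundant genes whose reads could not be split between libraries, so they were not tested. The ratio of the authors' means, iSPCH over WT, was 0.628 to 0.896 for them at 6 h and 0.558 to 0.813 at 8 h. At the most even split between libraries, which gives pairs the smallest spread they can have, limma called 0 higher and 5 lower at 6 h, and 0 higher and 8 lower at 8 h.

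Most hormone and cell cycle genes were not called. Among 18 brassinosteroid signalling genes BEH1 (AT3G50750) was lower by -0.57 ± 0.10 at 6 h and -0.57 ± 0.10 at 8 h, and BEH3 (AT4G18890) was higher by 0.71 ± 0.18 at 8 h, both relatives of the transcription factor BZR1. The list had 1 and 2 calls adjusted over the list alone (camera adjusted p = 0.487 and 0.787, adjusted p = 0.548 and 0.781 with an estimated correlation). At 6 h its median was 0.02, its mean -0.03 and camera's direction down. Of 11 brassinosteroid metabolism genes 1 was lower at 6 h, and 3 were lower and 1 higher at 8 h (1 and 6 adjusted over the list alone). Camera gave adjusted p = 0.0949 and 0.0466 (adjusted p = 0.321 and 0.295 with an estimated correlation). The biosynthetic gene CPD (AT5G05690) had -0.33 ± 0.09 and -0.50 ± 0.09. Of 33 cell cycle genes the D-type cyclin CYCD3;2 (AT5G67260) was higher at both hours, by 0.64 ± 0.08 and 0.79 ± 0.08, and CYCD3;1 (AT4G34160) at 8 h, by 0.97 ± 0.18. At 8 h 4 were lower, among them the mitotic gene CDC20.1 (AT4G33270), which has a near-identical copy, by -0.50 ± 0.11. The list had 1 and 6 calls adjusted over the list alone (camera adjusted p = 0.327 and 0.979, adjusted p = 0.548 and 0.988 with an estimated correlation), and at 8 h its median of -0.05 and mean of -0.02 were below 0 while camera's direction was up. Of 13 auxin and cytokinin genes the auxin exporters PIN7 (AT1G23080) and PIN3 (AT1G70940) were lower by -0.61 ± 0.08 and -0.87 ± 0.11 at 8 h, PIN7 also at 6 h by -0.47 ± 0.08. ARR16 (AT2G40670), a cytokinin response regulator, was higher by 2.71 ± 0.46 at 8 h. The list had 1 and 7 calls adjusted over the list alone (camera adjusted p = 0.207 and 0.0249, adjusted p = 0.548 and 0.396 with an estimated correlation). At 6 h CPD was lost in 12 of 22 alternatives (adjusted p = 0.334 without WT 6 h A) and BEH1 without WT 6 h A (0.0547). At 8 h BEH3 was lost without iSPCH 8 h A or WT 8 h A (adjusted p = 0.168 and 0.173) or with DESeq2 (0.0692), CDC20.1 without iSPCH 8 h A or WT 8 h B (0.0774 and 0.0817), and CYCD3;1 without WT 8 h A (0.0521). The camera calls at 8 h were lost without WT 8 h B for both lists (adjusted p = 0.132 for brassinosteroid metabolism and 0.207 for auxin and cytokinin) and for brassinosteroid metabolism without iSPCH 8 h A (0.179), with a mean CPM of at least 5 (0.129) or with abundant genes at their most even split (0.0502).

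Among lists for daily and stress responses, some defence genes were higher at 8 h and some clock genes lower. Of 10 touch, wound and defence genes 1 was higher at 6 h and 4 at 8 h (2 and 4 adjusted over the list alone). Camera gave adjusted p = 0.207 and 0.0313 (adjusted p = 0.548 and 0.396 with an estimated correlation). JAZ10 (AT5G13220), a jasmonate repressor, had 1.11 ± 0.20 and 1.71 ± 0.20. The zinc finger genes ZAT10 (AT1G27730) and ZAT12 (AT5G59820) had 1.19 ± 0.26 and 0.88 ± 0.19 at 8 h, and WRKY33 (AT2G38470) had 0.50 ± 0.13. Of 14 clock genes 2 were lower at 6 h and 5 at 8 h (4 and 6 adjusted over the list alone). Camera gave adjusted p = 0.0405 and 0.188 (adjusted p = 0.165 and 0.378 with an estimated correlation). The morning regulators CCA1 (AT2G46830) and LHY (AT1G01060) had -0.65 ± 0.14 and -0.60 ± 0.13 at 8 h. CDF1 (AT5G62430) had -0.99 ± 0.21 and -0.95 ± 0.21. In the hypoxia list 0 of 11 were called at 6 h (0 adjusted over the list alone) and 1 at 8 h (1 adjusted over the list alone), namely PDC1 (AT4G33070), a pyruvate decarboxylase, by 1.14 ± 0.24. Camera gave adjusted p = 0.207 and 0.0654 (adjusted p = 0.548 and 0.382 with an estimated correlation). Of 4 water deficit, cold and heat genes 0 were called at 6 h (0 adjusted over the list alone, camera adjusted p = 0.164, adjusted p = 0.321 with an estimated correlation). At 8 h the dehydration gene RD29A (AT5G52310) was lower by -1.07 ± 0.09 and the chaperone HSP101 (AT1G74310) higher by 0.63 ± 0.15 (3 adjusted over the list alone, camera adjusted p = 0.979, adjusted p = 0.988 with an estimated correlation). The list's median of 0.20 was above 0, with camera's direction down. Without iSPCH 8 h A the 8 h calls of ZAT10, ZAT12, WRKY33, CCA1, LHY, CDF1 and HSP101 were lost (adjusted p = 0.104, 0.0837, 0.190, 0.0731, 0.0769, 0.0817 and 0.177). Without WT 8 h B those of ZAT10, ZAT12, WRKY33, LHY, CDF1, PDC1 and HSP101 were lost (adjusted p = 0.0527, 0.0976, 0.294, 0.0544, 0.113, 0.0963 and 0.163). At 6 h JAZ10 was lost without WT 6 h A (adjusted p = 0.0683), and CDF1 without WT 6 h A, WT 6 h B or iSPCH 6 h B (0.107, 0.137 and 0.139). The camera call for defence genes was lost without iSPCH 8 h A or WT 8 h B (adjusted p = 0.317 and 0.132), and that for clock genes at 6 h without WT 6 h A or iSPCH 6 h A (0.187 and 0.217). With a mean CPM of at least 5 both were lost too (adjusted p = 0.346 and 0.0604).

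**Figure D4:**
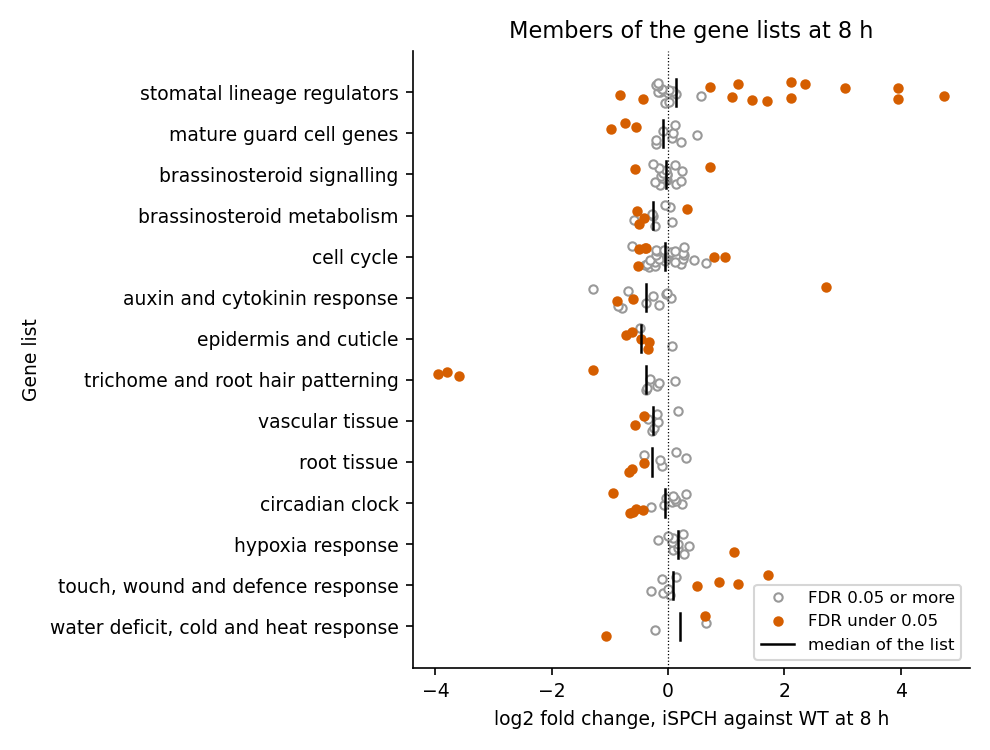
Log2 fold change between iSPCH and WT at 8 h of every tested member of 14 gene lists, with filled points for FDR under 0.05 and a vertical line at each list's median. The largest positive values are in the stomatal lineage list, up to 4.75 for EPF2, and the largest negative ones in the trichome and root hair list, down to -3.95 for COBL9.

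The 3 untreated libraries show what differed between the lines before induction. YSL2 (AT5G24380), a metal transporter of the YELLOW STRIPE-like family, was higher in iSPCH by 1.15 ± 0.15 (adjusted p = 0.00247), and AT5G35935 by 1.57 ± 0.15 (adjusted p = 0.000227). The glutathione transferase gene GSTF14 (AT1G49860) was lower by -1.96 ± 0.29 (adjusted p = 0.00805). So were the overlapping or neighbouring loci AT4G22510, AT4G22513 and AT4G22517, by -1.87 ± 0.22, -1.72 ± 0.26 and -1.75 ± 0.27. SPCH differed by 0.16 ± 0.23 (adjusted p = 0.929). Over all genes 9 were higher and 9 lower. Untreated WT is 1 library and was assumed to vary like the other groups. The count was 28 without iSPCH 0 h B, 41 without iSPCH 6 h A, 39 without iSPCH 6 h B, 44 with only the compared groups, 42 with DESeq2, 30 with no filter, and 34 (24 higher, 10 lower) with library size alone. GSTF14, AT4G22517 and AT4G22513 were no longer called without iSPCH 0 h B (adjusted p = 0.0630, 0.0902 and 0.0705).

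Averaged over 6 h and 8 h, which sets 4 libraries a line against each other, AT1G12845 was higher in iSPCH by 4.61 ± 0.09, EPF2 by 4.06 ± 0.27, TMM by 3.63 ± 0.08 and POLAR by 2.86 ± 0.11. The AT1G05240 and AT1G05250 pair was lower by -3.48 ± 0.23. AT4G08400 and AT4G08410, proline-rich wall proteins, were lower by -3.50 ± 0.81 (adjusted p = 0.0439) and -3.54 ± 0.85 (adjusted p = 0.0494). In all 1160 genes were higher and 1993 lower (3153). The count was 1990 without WT 6 h A, and library size alone gave 3484 higher and 1157 lower. The calls of AT4G08400 and AT4G08410 were lost without most single libraries, such as WT 6 h A (adjusted p = 0.117 and 0.127).

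Within WT, the treatment and the hours passed came with very large changes. THA1 (AT1G08630), a threonine aldolase, was higher than at 0 h by 7.86 ± 0.62 at 6 h and 8.38 ± 0.62 at 8 h. BCAT-2 (AT1G10070), an aminotransferase of branched-chain amino acids, was higher by 7.57 ± 0.16 and 8.23 ± 0.16, and BCB (AT5G20230), a blue copper-binding protein, by 7.08 ± 0.37 and 8.00 ± 0.37. The uncharacterised AT1G13650 was lower by -6.07 ± 1.29 and -6.03 ± 1.29, and the cysteine protease gene AT2G27420 by -5.14 ± 0.88 and -6.41 ± 0.88. At 8 h 25 of 33 cell cycle genes were lower and 2 higher (29 adjusted over the list alone, camera adjusted p = 0.000148, adjusted p = 0.299 with an estimated correlation). Of the 27 stomatal lineage genes 16 were lower and 5 higher (21 adjusted over the list alone, camera adjusted p = 0.0512, adjusted p = 0.349 with an estimated correlation). SPCH itself had -0.62 ± 0.23 at 6 h (adjusted p = 0.0493) and -0.59 ± 0.23 at 8 h (adjusted p = 0.0559). In all 5753 genes were higher and 5487 lower at 6 h, and 6140 higher and 5875 lower at 8 h. Of these, 4135 and 4903 changed at least 2-fold. There are no untreated seedlings at 6 h or 8 h, so the hour and the treatment cannot be separated, and the baseline is 1 library.

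Within iSPCH the same amino acid genes led the course. BCAT-2 was higher than at 0 h by 7.94 ± 0.13 at 6 h and 8.05 ± 0.13 at 8 h, and THA1 by 7.93 ± 0.51 and 8.15 ± 0.51. GLYI7 (AT1G80160), of the glyoxalase I family, was higher by 7.15 ± 0.10 and 7.42 ± 0.10, next to SPCH with 7.55 ± 0.19 and 7.67 ± 0.19. The extensin-like gene EXT13 (AT5G35190) was lower by -7.39 ± 0.86 at 8 h. CYP79F1 (AT1G16410), an enzyme of aliphatic glucosinolate synthesis, was lower by -5.17 ± 0.89 and -6.24 ± 0.89, with 0 and 4 reads at 8 h, so these folds depend on the added count. In all 6518 genes were higher and 6273 lower at 6 h, and 6837 higher and 6592 lower at 8 h. Of these, 4487 and 5169 changed at least 2-fold. Library size alone gave 8442 higher and 5274 lower at 8 h, with a shift of the median gene of 0.17.

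Whether the course since 0 h differed between the lines was tested directly. Over 6 h the changes of AT1G12845, EPF2 and TMM were larger in iSPCH by 4.15 ± 0.21, 3.37 ± 0.60 and 3.31 ± 0.17. Those of AT1G70820, a putative phosphoglucomutase, and AT4G16870 differed by -1.80 ± 0.17 and -1.57 ± 0.12. Over 8 h AT1G12845 and EPF2 differed by 5.72 ± 0.21 and 4.75 ± 0.60, and COBL9 and the AT1G05240 and AT1G05250 pair by -3.81 ± 0.52 and -3.91 ± 0.51. For 6 h 46 genes were called higher and 95 lower (141), and for 8 h 351 and 294 (645). The first count was 41 and 56 without WT 6 h A or B, 65 and 78 without iSPCH 0 h A or B, 280 without iSPCH 6 h A and 89 with no filter. EPF2 was no longer called over 6 h without WT 6 h A (adjusted p = 0.158), WT 6 h B (0.110) or iSPCH 0 h A (0.0908). The second count was 345 without iSPCH 8 h A, 407 without WT 8 h A, 392 and 419 without iSPCH 0 h A or B, and 490 higher and 231 lower with library size alone.

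From 6 h to 8 h within iSPCH, single genes known from defence were among the highest and single genes known from root hairs among the lowest. AT1G26410 and AT1G26380, of the berberine bridge enzyme-like family, were higher at 8 h by 4.61 ± 0.73 and 4.46 ± 0.80. CYP71A12 (AT2G30750), a cytochrome P450 of camalexin synthesis, held 226 and 28 reads at 8 h against 3 and 1 at 6 h. The small heat shock gene HSP17.6A (AT5G12030) held 316 and 52 against 13 and 1, so library A carried most of both. EXP7 was lower by -2.87 ± 0.32, the peroxidase gene AT1G30870 by -2.79 ± 0.25, and the arabinogalactan gene AGP3 (AT4G40090) by -2.54 ± 0.53. In all 780 genes were higher and 697 lower (1477). The count was 766 and 848 without iSPCH 8 h B or A, 841 with only the compared groups, and 1033 higher and 578 lower with library size alone. CYP71A12, HSP17.6A and AGP3 were no longer called without iSPCH 8 h A (adjusted p = 0.0639, 0.127 and 0.135), HSP17.6A without iSPCH 6 h B (0.121), and AGP3 without WT 6 h A, WT 6 h B or WT 8 h A (0.0603, 0.0617 and 0.0518). CYP71A12, HSP17.6A and AT1G26380 were not called by edgeR with TMM (adjusted p = 0.121, 0.0839 and 0.0527).

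The difference between the lines was itself higher at 8 h than at 6 h for 175 genes and lower for 45 (220). In the stomatal lineage list POLAR gained 2.18 ± 0.23 (adjusted p = 0.000569), BASL 1.90 ± 0.30 (adjusted p = 0.00579), ERL1 1.29 ± 0.27, TCX2 0.90 ± 0.16, SCRM2 0.67 ± 0.11 and ICE1 0.51 ± 0.11. These 6 of 27 were called higher and 0 lower (12 adjusted over the list alone, camera adjusted p = 8.78e-06, adjusted p = 0.203 with an estimated correlation). TMM and EPF2, with 0.66 ± 0.16 and 1.39 ± 0.54, were not past the threshold (adjusted p = 0.0593 and 0.408). The root hair regulator LRL3 (AT5G58010) differed by -2.15 ± 0.33, AT1G30870 by -2.49 ± 0.35 and AT2G34910, a root hair specific protein, by -2.10 ± 0.31. The count was 106 and 119 without WT 6 h A or B, 127 without iSPCH 8 h A and 136 without WT 8 h A.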

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

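The tests of scaling, of single libraries and of the lines before induction, and those of root tissue and of SPCH transcript, were chosen only after the result was seen, and the bound for root tissue was rewritten after a first one had left the question open. The first tests of scaling and single libraries used genes chosen for the pattern or scalings that could not have shown the opposite, and were replaced, that of scaling more than once. Those of the shallow library and of other splits were set before. No group has 4 or more libraries, so no library was tested as an outlier, and no column was left unused.

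The change from 0 h to 6 h differed between the lines for 141 genes by a direct test of the difference. Named among them are SPCH (8.16), AT1G12845 (4.15), EPF2 (3.37), TMM (3.31) and AT2G25460 (2.35), higher in iSPCH. AT4G16880 (-1.95), AT3G55240 (-1.88), AT1G70820 (-1.80), AT4G16870 (-1.57) and AT2G25200 (-1.53) were lower. Calls were lost for AT4G16880 in 5 of 21 alternatives (adjusted p = 0.136 without WT 6 h A), AT3G55240 in 4 of 21 and EPF2 in 3 of 21. From 0 h to 8 h the difference was past the threshold for 645 genes. They include SPCH (8.26), AT1G26380 (6.69), AT1G12845 (5.72), EPF2 (4.75) and AT1G26410 (4.51). Lower were RHS8 (-3.92), AT1G05250 (-3.91), AT1G05240 (-3.91), COBL9 (-3.81) and PRP3 (-3.54). AT1G26380 and AT1G26410 had 0 to 4 reads a library at 0 h, so their fitted values depend on the added count. Calls were lost for AT1G26410 in 12 of 20 alternatives (adjusted p = 0.99994 with edgeR) and AT1G26380 in 4 of 21 (0.515 with edgeR). RHS8 was lost in 8 of 21 (0.330 with an added count of 0.1) and PRP3 in 7 of 22 (0.110 without iSPCH 8 h A).

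The line difference itself differed between 8 h and 6 h for 220 genes. Stomatal genes with a larger difference at 8 h were POLAR (2.18), BASL (1.90), ERL1 (1.29), TCX2 (0.90), SCRM2 (0.67) and ICE1 (0.51), and so was AT1G12845 (1.57). Genes tied to defence were CYP71A12 (5.52), AT1G26380 (5.46), AT1G26410 (5.17), NAC042 (3.63) and AT5G57010 (3.14), with 1 to 21 reads a library at 6 h. Root hair and wall genes were AT1G30870 (-2.49), EXP7 (-2.38), COBL9 (-2.31), LRL3 (-2.15), AT2G34910 (-2.10) and AT2G47540 (-2.01). Others were CSD2 (-1.64), CCS (-0.95), FSD1 (0.50), YSL2 (0.96), RD29A (-1.12), GLYI7 (-0.89) and AT1G70820 (0.79). Several of these calls were not stable. All 7 were tested in 21 alternatives, as their mean CPM is under 5. CYP71A12 was no longer called in 13, AT1G26380 in 12, AT5G57010 in 11, COBL9 in 8, AT1G26410 in 7, EXP7 in 6 and NAC042 in 5. edgeR gave an adjusted p of 0.669 for CYP71A12 and of 0.494 for AT1G26380. Without iSPCH 8 h A, the library with the most reads of both, adjusted p was 0.271 and 0.148.

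The berberine bridge, glutathione transferase tau and WRKY families had more genes higher in iSPCH at 8 h than expected, with medians over all members of 0.59, 0.62 and 0.20. Other scalings moved the median gene by up to 0.12 and left all 3 past the threshold (adjusted p up to 0.00287), but both raise iSPCH. The medians of 0.59 and 0.62 lie above 0.12, so a shift of that size alone would not give them in the first 2 families. The WRKY median of 0.20 lies near it, so there scaling and a true rise cannot be told apart. The lower quartiles of -0.06, -0.18 and -0.0014 show that members of all 3 families went both ways. The bound written for this test also asked for lower quartiles above the shift, so the test left scaling undecided for all 3. With 1 library at 8 h left out adjusted p was at most 3.88e-05 for the berberine bridge and glutathione transferase families, which argues against a single library as the whole cause, although the berberine bridge median was 0.29 without iSPCH 8 h A. The WRKY call was lost without iSPCH 8 h A, WT 8 h A or WT 8 h B (adjusted p = 0.107, 0.0584 and 0.383, medians 0.20, 0.21 and 0.23), where a single library and too few libraries cannot be told apart. At 0 h the median of the 27 members called at 8 h was 0 (quartiles -0.08 and 0.18), against 0.84 at 8 h. This argues against a difference of that size from before induction, for members with enough reads at 0 h. AT1G26380 and AT1G26410 had too few reads there to bear on this. Limma called 0 of 27 at 0 h, which adds little, as it called only 18 of 19660 genes there. A response to SPCH and an effect of other parts of the construct cannot be told apart here, and neither was tested.

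The 17 root hair genes are a family of 12 found by its drop at 8 h and the 5 root hair genes of the patterning list fixed in advance, with medians of -2.16 for all and -3.60 for the 5. The root tissue list had a median of -0.28 (lower quartile -0.47), which argues against a loss of whole roots, while a loss of the part of the root that bears hairs stays open. The median of the 5, against a largest scaling shift of 0.12, argues against scaling. At 0 h the median was -0.20 for all 17 and -0.19 for the 5, which argues against a difference of that size from before induction. Several of these genes also fell in WT after 0 h. Repression of hair genes by SPCH may be one explanation of the further drop in iSPCH, and it was not tested.

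The 12 stomatal genes called higher at 8 h, a choice that favours a further rise, had a median further rise of 0.96 after 6 h, against 0.18 over all 27 tested. Without the shallow library, iSPCH 6 h B, it was 0.89 for the 12, which argues against that library as the cause. SPCH transcript in iSPCH differed by 0.12 (SE 0.19, shared with other genes) between the hours, and both libraries at 8 h lay above both at 6 h. Its amount at 6 h and the longer time for targets to accumulate cannot be told apart here, because 2 SE above the difference just reaches 0.5 times the further rise, and SPCH protein was not measured.

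For the mean of 6 h and 8 h, 1 of the 35 splits of the 8 libraries into 4 and 4 gave as many genes as the split by line, which was that split itself. With 35 splits no stronger statement against chance is possible. In that fit, without the hour, the split by line gave 1196 genes and the highest of the other splits 208. The latter set iSPCH 6 h A, WT 6 h A, WT 6 h B and WT 8 h B against the rest. The split by hour gave 2.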

How the results depend on the processing

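TMM scaling, no robust variance and the most even split of abundant genes were tests chosen only after the result was seen, and the rest were planned. SPCH was past the threshold in all 22 alternatives, at 8.16 to 8.49 for 6 h and 8.17 to 8.66 for 8 h. The 217 named gene results had 4690 values under the 22 alternatives, fewer where a filter removed the gene or a tool gave no value. Of these, 4348 were on the same side of the threshold, 342 were no longer past it and 0 reversed. Most were lost without WT 8 h B (38 of 217) and WT 6 h A (36 of 217).

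Counts within 1.5 times the reported one are left out here. With an FDR of 0.01 counts were 330 (6 h), 1068 (8 h), 1626 (mean of both), 38 and 235 (difference of the change to 6 h and 8 h), 687 (iSPCH 8 h against 6 h) and 97 (line difference, 8 h against 6 h). With a 2-fold minimum they were, in the same order, 132, 413, 254, 66, 254, 275 and 114. Within lines they were 4487 and 5169 (iSPCH) and 4135 and 4903 (WT). Stricter thresholds lower counts by construction. With only the compared groups, and so fewer libraries for the spread, counts were 538 (6 h), 44 (0 h) and 841 (iSPCH 8 h against 6 h). At 0 h library size alone gave 34, no filter 30 and DESeq2 42. With no filter the difference of the change to 6 h gave 89. For these the cause was not tested.

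Leaving out 1 library gave 228 to 1407 genes at 6 h, 1112 to 2524 at 8 h, 1990 to 3513 for the mean, 19 to 41 at 0 h, 41 to 280 and 345 to 954 for the differences of the change, 766 to 1484 for iSPCH 8 h against 6 h, and 106 to 319 for the line difference between the hours. A lone library was assumed to vary like the other groups, and the cause was not tested. Camera called 6 lists at 6 h and 7 at 8 h. It called 3 at 6 h with a mean CPM of at least 5, 0 at both hours with an estimated correlation, 4 to 7 at 6 h with a library left out, and 4 (without WT 8 h B) to 8 (without iSPCH 8 h B) at 8 h with a library left out. Another planned list test, fry, gave p values that depended on the order in which groups entered the model, so they are not given.

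No paired analysis was possible because the replicate numbers could not be traced to the recovered libraries. Depth limits genes with few reads, whose folds move with the added count, and recovery limits the 118 abundant genes.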

Other observations

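The families and copper-related genes in this part were tests chosen only after the result was seen. Product names were grouped into 200 families of 12 to 400 tested genes, and each was tested for more calls than expected. The test takes genes as independent, but members of a family can vary together, so its p values can be too small. Some loci also share reads, as the peroxidase genes AT1G05240 and AT1G05250 do, and are still counted singly. At 8 h 8 families had more genes called higher in iSPCH, led by the berberine bridge family (9 of 17, adjusted p = 4.05e-06), glutathione transferases of the tau class (7 of 13, adjusted p = 4.74e-05) and WRKY proteins (11 of 37, adjusted p = 4.74e-05). The WRKY call was lost without iSPCH 8 h A, WT 8 h A or WT 8 h B (5, 6 and 4 of 37, adjusted p = 0.107, 0.0584 and 0.383). Also at 8 h, 9 families had more called lower, led by peroxidases (15 of 49, adjusted p = 1.74e-05) and the 3-ketoacyl-CoA synthases (8 of 16, adjusted p = 0.000105). At 6 h 2 families had more called lower, the 3-ketoacyl-CoA synthases (8 of 16, adjusted p = 4.80e-06) and the NPH3 family (7 of 28, adjusted p = 0.00422), and 0 had more called higher.

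Some genes of copper and superoxide handling were picked for their values and are given as values only, since no group was tested. CCS (AT1G12520) had -0.94 ± 0.12 at 0 h and -0.78 ± 0.10 at 8 h, CSD2 (AT2G28190) -1.13 ± 0.19 (adjusted p = 0.0731) and -1.30 ± 0.15, and CSD1 (AT1G08830) -0.81 ± 0.14 and -0.32 ± 0.11 (adjusted p = 0.0898 at 8 h). FSD1 (AT4G25100) had 0.77 ± 0.09 and 0.68 ± 0.08, and YSL2 had 1.15 ± 0.15 and 0.69 ± 0.12. At 6 h CSD2 had 0.34 ± 0.15 (adjusted p = 0.275). From 6 h to 8 h the line difference changed by -1.64 for CSD2, -0.95 for CCS, 0.50 for FSD1 and 0.96 for YSL2. The values at 0 h and 8 h therefore do not show a difference that held at 6 h.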
